A study of Homo sapiens with 6 samples.

How the data were processed

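Total RNA from 6 samples of HT29, an established human colorectal carcinoma line, was measured by RNA sequencing, 3 samples labelled as control hairpin and 3 as ETV5 hairpin. Samples were grouped by their labels. The treatment field of the labels names the ETV5 lentivirus for every sample, controls included, so the groups rest on the sample titles and source names, which give a control and an ETV5 hairpin. The labels number the samples 1 to 3 in each group without saying whether a number stands for a culture, a batch or a hairpin. Nothing in the sources used here says that replicates were separate cultures.

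The authors deposited a table of read counts per gene, in whole numbers, with 41762 features, a feature type for each and 1 column per library. Per the submitters' processing notes, reads were aligned with HISAT2 and the genome build was GRCh38. The RNA selection, the counting tool, the strand setting and the annotation release are not given in the sources used here. Without a strand setting, antisense and overlapping genes are uncertain, as are genes with near-identical copies such as histones, ribosomal proteins, HLA genes and the AKR1C family, and without the RNA selection counts of snoRNAs are uncertain too. The table held no blank or total rows and no repeated names, and 25119 features had at least 1 read. Total counts were 26684548, 30693089 and 26333983 in the controls and 24262066, 27380515 and 27910573 in the knockdown libraries. Messenger RNAs took 94.8% to 95.4% of the counts and ribosomal RNA 1.53% to 2.01%. At these depths 1 CPM stands for 24.3 to 30.7 counts before scaling, and genes with few counts carry the widest counting error.

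From the counts, genes were filtered with edgeR's filterByExpr, which left 15669, and libraries were scaled by TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 21.7%. Values per gene are CPM from TMM-scaled library sizes, given as mean ± SD over n = 3. For 4 named genes with 0 to 3 counts over the control group, folds were taken from summed counts over scaled library sizes, with a floor of 3 counts or an exact 95% binomial counting interval. ETV5 was also compared by an exact permutation test. All scalings tried left the median log2 fold change of all genes within 0.1 of 0.

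Before the data were examined, 29 gene lists with 864 places were fixed, of which 862 were found in the table by current or older symbols. ETV5 was left out of the list tests. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were run with a correlation estimated for each list, and with fry, which tests whether a set's genes move on balance in a direction without comparing it with other genes. A list of HT29 epithelial genes was fixed as a marker check, and lists of antigen presentation and NRF2 target genes were chosen after the data were seen.

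Named genes were chosen by a rule fixed before the data were examined. It took ETV5, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM in a group and no overlap between groups. It added up to 4 members of each list by p, 12 fixed genes, and the 3 non-coding genes with the smallest adjusted p in each direction. Coordinates are 1-based and come from RefSeq's annotation of GRCh38, matched by symbol. Genes outside the rule are said to be so where they are named, and some results for single genes are not reported here.

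Alternatives fixed in advance were median-ratio size factors, upper-quartile factors and library size alone for scaling, DESeq2 1.42.0, limma-voom and a robust quasi-likelihood fit as tests, no filter and a filter of 1 CPM in 3 libraries, a replicate block, and each library left out in turn. A comparison of controls 1 and 3 with knockdown 2 and 3 was added after control 2 and knockdown 1 were seen to stand apart. GC content was not checked, since no genome sequence was used here.

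The tests were tested on simulated data for this comparison, drawn from the real genes' means with 50 changed genes of each fold size. With a spread as among all 6 libraries and 15453 genes run, edgeR recovered 10%, 48%, 88% and 94% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, with 9 false calls. DESeq2 made 48 false calls over 15669 genes. With a spread as among the 4 closer libraries and 15487 genes run, edgeR recovered 70%, 88%, 96% and 98%. Genes were drawn independently, and a far smaller share was changed than the 16.5% called in the real data. These rates and false calls therefore need not hold for the real libraries. In a simulation that raised the G2/M list 2-fold, camera called that list and none of the others. Genes were drawn independently there, whereas the estimated correlation within the real G2/M list was 0.786. The simulation therefore cannot show how camera with the preset correlation behaves for genes that vary together. Figures were drawn with matplotlib 3.10.9.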

Results

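RNA from the human colorectal carcinoma line HT29 was sequenced after lentiviral delivery of short hairpin RNAs. Libraries from cells with a control hairpin (n = 3) were set against libraries from cells with a hairpin against ETV5 (n = 3), an ETS-family transcription factor of the PEA3 group that is induced by MAPK signalling. The control libraries held 26684548, 30693089 and 26333983 counts, and the knockdown libraries 24262066, 27380515 and 27910573. Of 41762 features, 15669 passed the low-count filter and were tested. The comparison asks which genes and pathways differ when ETV5 is reduced, and the values are CPM, counts scaled to library size by TMM, with log2 fold changes given as knockdown minus control.

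ETV5 mRNA was lower in all 3 knockdown libraries than in any control. In HT29 cells with the ETV5 hairpin, 35 of 36 measured interferon response genes fell (at least 20 without any single library), as did 11 of 21 NF-kB targets (at least 7). The immediate-early genes FOS, EGR1 and JUN rose, together with the intestinal stem cell marker LGR5 and MYC. Counts for genes of the unfolded protein response (12 of 30 lower) and of the G2/M phase (11 of 54 higher) depended on which libraries entered. For the first, 0 were lower without control 1 or control 3 and 26 without knockdown 1. For the second, 0 were higher without control 3 and 30 without control 2. Calls over all genes changed as well, to 529 without control 1, 1773 without control 2, 415 without control 3 and 6362 without knockdown 1. The median log2 fold changes kept their direction without any single library. They ranged from -1.65 to -0.79 for the first list and from 0.75 to 1.41 for the second. HEPACAM2 and the endocrine transcription factors NEUROG3 and PAX4, all near the floor in the controls, were higher in each knockdown library. Each was far lower in knockdown 1 than in knockdown 2 and 3, with NEUROG3 at 0.639, 8.64 and 6.96 CPM. In all, 2584 genes changed, 1299 upward and 1285 downward, and the number ranged from 415 to 6362 when a library was left out.

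ETV5 (chromosome 3, 186046314 to 186109089, GRCh38) stood at 89.8, 529.7 and 85.1 CPM in controls 1, 2 and 3 and at 26.0, 26.4 and 29.0 CPM in the knockdown libraries. The group means were 234.9 ± 255.3 and 27.2 ± 1.64 CPM (SD, n = 3 each), a log2 fold change of -3.11 ± 0.72 (SE) with an adjusted p of 0.0299 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Control 2 held 6.06 times the mean of the other controls, so the mean reduction was 8.65-fold with all controls and 3.22-fold against controls 1 and 3 alone. The edgeR call was lost without knockdown 2 (adjusted p = 0.0948) and without knockdown 3 (adjusted p = 0.106). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries can give.

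**Figure D1:**
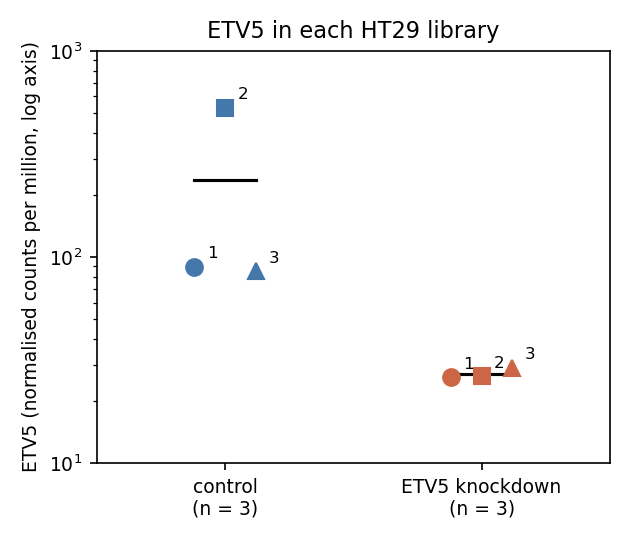
ETV5 in CPM (log axis) in each of the 6 HT29 libraries, with replicate numbers beside the points and a bar at each group mean. The knockdown libraries lay between 26.0 and 29.0 CPM, controls 1 and 3 at 89.8 and 85.1 CPM, and control 2 at 529.7 CPM.

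The close relatives of ETV5 did not pass the test with all 6 libraries. With a library left out, the lowest edgeR adjusted p was 0.0585 for ETV1 and 0.000583 for ETV4. In knockdown 1, 2 and 3 ETV4 stood at 70.5, 139.8 and 134.1 CPM, so its result depended on knockdown 1. ETV1 had 9.19 ± 3.53 CPM in the controls and 15.1 ± 5.08 CPM in the knockdown (SD, n = 3 each; edgeR adjusted p = 0.205), and ETV4 had 79.6 ± 1.69 and 114.8 ± 38.5 CPM (edgeR adjusted p = 0.169). In the list of 20 other ETS factors, ETS2 rose from 366.6 ± 23.3 to 937.9 ± 173.0 CPM and ELF5, ELF2 and ETV6 fell, with the same counts, 1 and 3, when adjusted over the list alone. Without a library the adjusted p reached 0.108 for ELF5, 0.156 for ELF2 and 0.158 for ETV6. Without knockdown 1, 2 members rose and 8 fell; none fell without control 1, control 3, knockdown 2 or knockdown 3, and 1 fell without control 2. The list as a whole was not called (camera adjusted p = 0.603).

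The transcriptome separated by group along the main axis of variation. The first principal component held 62.8% of the variance, with the controls between -48.0 and -44.6 and knockdown 2 and 3 at 62.1 and 60.5. Knockdown 1 lay at 15.8 on that axis and alone on the second component, which held 18.01%. The third, with 12.4%, set control 2 apart. Library pairs within these groups were unequal. Controls 1 and 3 correlated across genes at 0.9933 and knockdown 2 and 3 at 0.9929. Control 2 and knockdown 1 correlated with their own groups at 0.9808 and 0.9676 at most. Control 2 reached 0.9552 at most with a knockdown library. Knockdown 1, however, correlated about as well with control 1 (0.9618) as with knockdown 2 (0.9634).

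**Figure D2:**
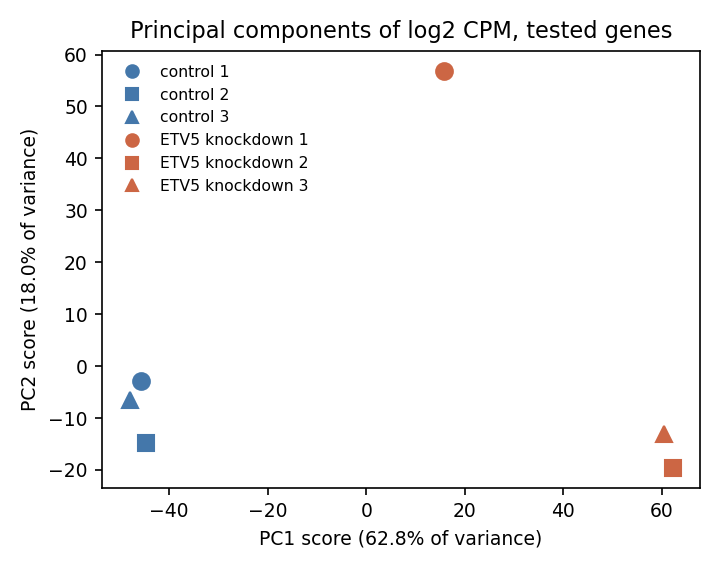
Principal component scores of the 6 libraries from log2 CPM of all tested genes, the first component (62.8% of the variance) on the horizontal axis and the second (18.01%) on the vertical. The controls lie together at the left, knockdown 2 and 3 at the lower right and knockdown 1 between them at the top.

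The test found 16.5% of the 15669 genes changed, and 1188 of these differed at least 2-fold (607 higher, 581 lower). Groups did not overlap for 6182 genes, or 39.5%, where chance gives 10%. The number of calls depended on which libraries entered. It was 529 without control 1, 1773 without control 2 (1502 of them among the 2584), 415 without control 3, 864 without knockdown 2 and 522 without knockdown 3, but 6362 without knockdown 1 and 8563 in the 4 libraries left when control 2 and knockdown 1 were both set aside. All 2584 genes kept their call and direction in that last comparison, which was added after the data were seen. It used the closer libraries of the same data, so this is no separate support for the calls. Counts of list members without a library, given below, are to be read beside the totals over all genes. Of 111 genes other than ETV5 that were named by the fixed rule and passed the test, 50 passed in each of the 6 comparisons that left out a library; among the others, the highest adjusted p without a library is given where the gene is described.

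Interferon-induced genes made up 5 of the 10 largest falls by the fixed rule, namely IFI27, OAS2, IFI6, IFI44 and BST2 (tetherin, which holds budding virus at the cell surface). IFI27 (chromosome 14, 94105894 to 94116690) went from 35.6 ± 9.45 to 0.848 ± 0.231 CPM, a log2 fold change of -5.39 ± 0.31 (SE; edgeR adjusted p = 0.000981). OAS2, a sensor of double-stranded RNA, went from 12.6 ± 2.16 to 0.161 ± 0.117 CPM. OAS1 (chromosome 12, 112906962 to 112933219) fell from 58.6 ± 9.12 to 9.57 ± 1.22 CPM and IFI44L from 5.53 ± 0.751 to 0.050 ± 0.0207 CPM. Of the 36 interferon response genes measured, 35 fell and none rose, and all 36 were lower when adjusted over the list alone. Their median log2 fold change was -2.06, and the mean of the list was lower in each knockdown library than in each control. The list was called by camera (adjusted p = 8.6e-27), with adjusted p = 0.139 with an estimated correlation. The number of members that fell was 20 without control 1, control 3 or knockdown 3 and 24 without knockdown 2. The immune markers CD14 and CD8A fell as well, from means of 2.53 and 1.20 CPM to 0.529 and 0.329 CPM.

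Among NF-kB targets, RELB, a subunit of NF-kB that its own pathway induces, fell from 31.6 ± 5.40 to 8.07 ± 0.114 CPM, and NFKBIA, the pathway's inhibitor, from 53.7 ± 7.98 to 27.1 ± 1.78 CPM. TNFAIP2, CXCL1 and IL8 (the chemokine CXCL8) fell by 2.83, 2.08 and 3.74 on the log2 scale. LCN2 (lipocalin, an iron-scavenging acute-phase protein; chromosome 9, 128149453 to 128153453) fell from 582.6 ± 156.8 to 36.3 ± 30.2 CPM. In the list, 11 of 21 members fell and none rose, against 12 lower and 2 higher when adjusted over the list alone. Camera called the list (adjusted p = 3.2e-06), with adjusted p = 0.636 with an estimated correlation. The count of members that fell was 7 without knockdown 3 and 8 without control 1, control 3 or knockdown 2, and 2 members rose without control 2 and 1 without knockdown 1. SERPINA3, an acute-phase protease inhibitor, KLK10, a secreted kallikrein protease, and TNC, the matrix protein tenascin, completed the 10 largest falls. Their means went from 55.2, 90.8 and 36.7 CPM to 1.78, 1.60 and 2.74 CPM.

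**Figure D3:**
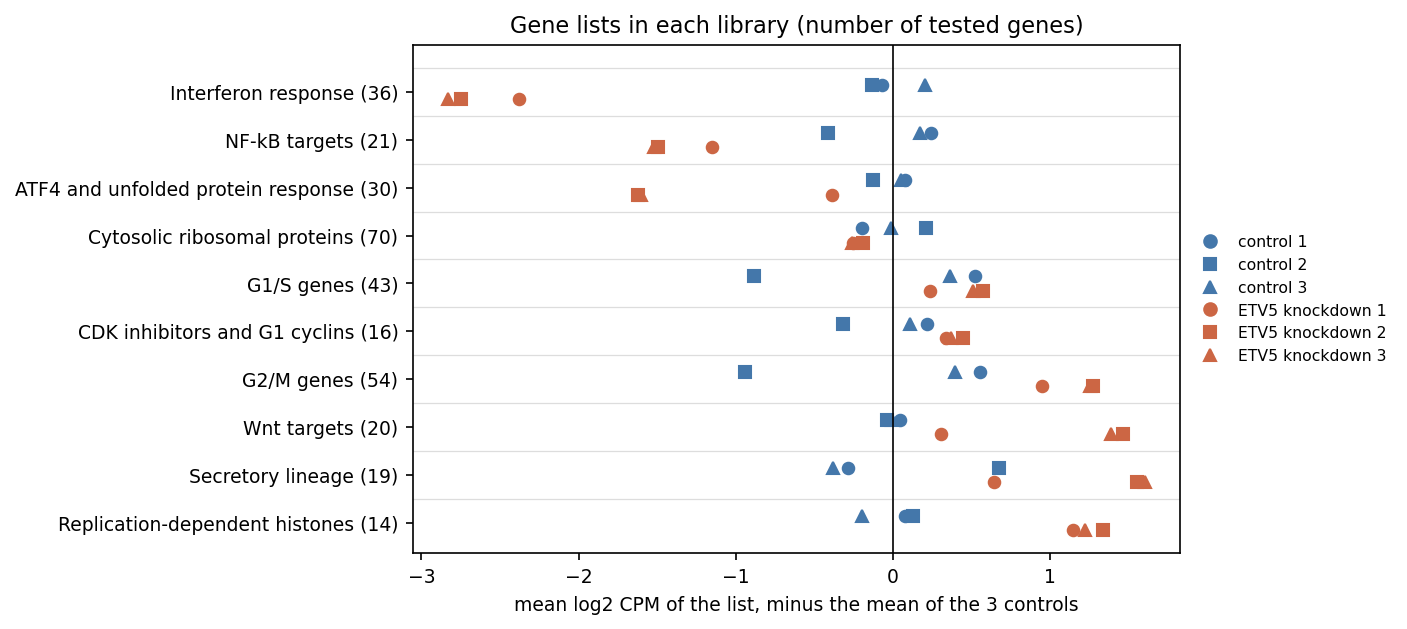
Mean log2 CPM of 10 gene lists in each library after subtraction of the mean of the 3 controls, with the number of tested genes in brackets, controls in blue and ETV5 knockdown in orange. Interferon response, NF-kB targets and the unfolded protein response were lower in all 3 knockdown libraries than in any control. Histones, G2/M genes, Wnt targets and CDK inhibitors with G1 cyclins were higher in all 3. Control 2 lay low for G1/S and G2/M genes. Knockdown 1 lay near the controls for the unfolded protein response and Wnt targets, though outside their range.

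Among genes of the ATF4 and unfolded protein responses, 12 of 30 fell and none rose, with 19 lower when adjusted over the list alone. CRELD2, a protein of the endoplasmic reticulum, had 124.3 ± 24.4 CPM in the controls and 46.0, 13.8 and 11.8 CPM in knockdown 1, 2 and 3. SLC3A2, a subunit of amino acid transporters, went from 855.0 ± 28.0 to 281.2 ± 147.8 CPM, and its partner SLC7A5 from 416.8 ± 17.1 to 227.2 ± 36.2 CPM. Camera called the list (adjusted p = 5.9e-09), with adjusted p = 0.836 with an estimated correlation. Knockdown 1 lay near the controls here, at a list mean of 7.86 log2 CPM against 8.12 to 8.32 in the controls and 6.62 and 6.64 in knockdown 2 and 3. Without knockdown 1, 26 members fell. Without control 1 or control 3 none did, without knockdown 2 or knockdown 3 it was 1, and without control 2 it was 4. The median log2 fold change was -0.91 with all libraries, -0.89 without control 1, -0.94 without control 3 and -1.65 without knockdown 1. The highest adjusted p without a library was 0.0889 for CRELD2, 0.0796 for SLC3A2 and 0.0510 for SLC7A5.

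Among outputs of MAPK signalling, the transcription factors FOS, EGR1 and JUN rose. FOS (chromosome 14, 75278828 to 75282230) went from 16.1 ± 2.26 to 77.2 ± 4.11 CPM, a log2 fold change of 2.26 ± 0.14 (SE; edgeR adjusted p = 0.000981). EGR1 went from 38.5 ± 9.85 to 168.4 ± 26.0 CPM and JUN from 94.9 ± 9.28 to 243.9 ± 11.8 CPM. TGFA, a ligand of the EGF receptor, fell from 92.1 ± 5.61 to 51.9 ± 6.23 CPM, and the immediate-early response gene IER3, named after its values were seen, fell by 0.53 on the log2 scale (edgeR adjusted p = 0.0355). DUSP6 and SPRY4, feedback inhibitors of the pathway, had log2 fold changes of 0.39 ± 0.32 and 0.83 ± 0.32 and did not pass (edgeR adjusted p = 0.430 and 0.111). With a library left out, the lowest edgeR adjusted p was 0.0541 for DUSP6 and 0.00122 for SPRY4. In knockdown 1, 2 and 3 SPRY4 stood at 50.5, 128.8 and 110.3 CPM. In the list of 30 genes, 6 rose and 5 fell (8 and 5 when adjusted over the list alone), and camera did not call it (adjusted p = 0.0906). Without knockdown 1, 11 rose and 8 fell. The number that rose was 3 without control 1 or control 3 and 4 without knockdown 2 or knockdown 3, and between 1 and 3 fell in these.

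**Figure D4:**
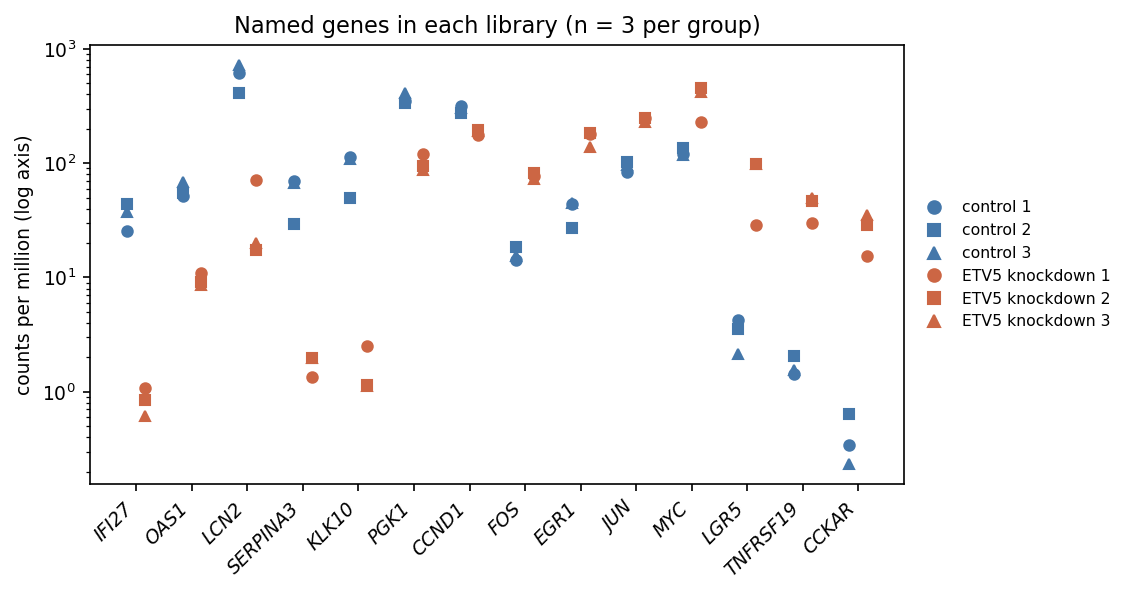
CPM (log axis) of 14 named genes in each library, controls in blue and ETV5 knockdown in orange (n = 3 each). The groups did not overlap for any of these genes, and LGR5 and MYC were lower in knockdown 1 than in knockdown 2 and 3.

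Among Wnt targets, 7 of 20 rose and 1 fell, with 11 and 1 when adjusted over the list alone. LGR5, a marker of intestinal stem cells (chromosome 12, 71439129 to 71586310), had 3.31 ± 1.07 CPM in the controls and 28.9, 98.3 and 98.6 CPM in knockdown 1, 2 and 3. TNFRSF19 went from 1.68 ± 0.334 to 42.1 ± 10.5 CPM, a log2 fold change of 4.64 ± 0.26 (SE; edgeR adjusted p = 0.000981). MYC went from 124.8 ± 9.20 to 368.4 ± 120.5 CPM, with a highest adjusted p of 0.0587 without a library. CCND1, which encodes cyclin D1, moved the other way, from 297.1 ± 21.5 to 188.9 ± 10.9 CPM (edgeR adjusted p = 0.0109, at most 0.0690 without a library). Camera called the list (adjusted p = 0.00145), with adjusted p = 0.836 with an estimated correlation. Knockdown 1 lay near the controls for this list, at 4.62 log2 CPM against 4.28 to 4.36 in the controls and 5.70 to 5.78 in knockdown 2 and 3. The number that rose was 15 without knockdown 1, 2 without control 1 or control 3, and 3 without control 2, knockdown 2 or knockdown 3.

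In the secretory list 8 of 19 genes rose and 3 fell (9 and 3 when adjusted over the list alone), and camera did not call it (adjusted p = 0.0514). KLK10, with 1 of the largest falls of all genes, is a member, as are NEUROG3, SPINK4 and LYZ, which rose. The largest rises by the fixed rule were in other genes. PAX4, a transcription factor of endocrine progenitors (chromosome 7, 127610292 to 127618142), had 0 counts in each control and 0.359, 24.2 and 19.7 CPM in the knockdown libraries, at least 421-fold higher against a floor of 3 counts over the control group. NEUROG3, which directs cells to the endocrine lineage, had 1 count over the 3 controls and 442 over the knockdown libraries, a ratio of 462.7 with a 95% counting interval from 82.6 to 18318. SPINK4, a product of goblet cells, had 1 count against 234 (ratio 245.0, 95% counting interval 43.5 to 9717). OR51E1, an olfactory receptor found in enteroendocrine cells, had 2 counts against 1312 (ratio 686.8, 95% counting interval 189.7 to 5677). These pooled counts came mostly from knockdown 2 and 3. In knockdown 1, 2 and 3 NEUROG3 had 0.639, 8.64 and 6.96 CPM and SPINK4 0.519, 4.17 and 3.92 CPM. OR51E1 had 3.12, 21.4 and 23.7 CPM there. HEPACAM2 went from 0.0742 ± 0.0407 to 24.9 ± 18.5 CPM and the cholecystokinin receptor CCKAR from 0.405 ± 0.214 to 26.6 ± 10.3 CPM. Beside TNFRSF19 and LGR5, the remaining largest rises were those of IHH, a hedgehog ligand of the gut epithelium, UGT2B15, a glucuronidating enzyme, NEURL1 and the non-coding GPC5-AS1, with log2 fold changes of 4.66, 6.28, 5.74 and 7.04. GPC5-AS1 was highest in knockdown 1, at 58.8 CPM against 8.09 and 6.24, and the others were highest in knockdown 2 or 3. The number of rises in the secretory list was 1 without control 1, 0 without control 3, 4 without knockdown 2 and 3 without knockdown 3, and 1 gene fell without control 1, control 3 or knockdown 3. LYZ, which encodes lysozyme, rose from 843.3 ± 38.7 to 1908 ± 378.1 CPM. Without a library the adjusted p reached 0.106 for PAX4, 0.0769 for NEUROG3, 0.0627 for SPINK4, 0.0507 for LYZ, 0.0710 for UGT2B15 and NEURL1 and 0.0659 for GPC5-AS1. Intervals and floors cover counting error only.

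Markers of absorptive cells that changed went in both directions. The glucose transporter SLC5A1 fell from 23.6 ± 1.03 to 4.13 ± 0.666 CPM and the keratin KRT20 from 452.7 ± 118.6 to 87.2 ± 47.6 CPM, with adjusted p up to 0.0529 without a library for KRT20. The transcription factor HNF4A rose from 22.1 ± 3.94 to 44.8 ± 11.9 CPM and the fatty acid binding protein FABP1 from 0.119 ± 0.0380 to 0.932 ± 0.312 CPM, with adjusted p up to 0.112 and 0.0627. In the list of 15, 2 rose and 2 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.318). Without knockdown 1, 3 rose and 7 fell; without control 3 or knockdown 3 none rose and 1 fell, and without control 1, 1 rose and 2 fell.

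Control 2 contributed to a difference in proliferation genes. Of 54 G2/M genes 11 rose and none fell, and 34 were higher when adjusted over the list alone, with a median log2 fold change of 1.09 (camera adjusted p = 4.8e-11, adjusted p = 0.836 with an estimated correlation). GAS2L3 rose from 4.94 ± 0.450 to 14.2 ± 3.39 CPM and RANGAP1, which activates the Ran GTPase, from 79.4 ± 0.919 to 127.1 ± 12.6 CPM. MKI67, the proliferation marker Ki-67, went from 113.2, 29.4 and 94.4 CPM in the controls to 280.8 ± 94.3 CPM (edgeR adjusted p = 0.0434). Control 2 had a G2/M list mean of 3.58 log2 CPM against 5.07 and 4.91 in controls 1 and 3. Without it the median was 0.75 and 30 members rose. The number was 2 without control 1, 0 without control 3, 22 without knockdown 1, 2 without knockdown 2 and 1 without knockdown 3. In these comparisons the median lay between 1.04 and 1.41. Without a library the adjusted p reached 0.0509 for GAS2L3, 0.0682 for RANGAP1 and 0.129 for MKI67.

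For G1/S genes, control 2 decided the result. No member of 43 passed, over all genes or when adjusted over the list alone, although 0.31 was the mean log2 fold change and camera called the list higher (adjusted p = 0.0287, and adjusted p = 0.836 with an estimated correlation). Control 2 stood at a list mean of 3.57 log2 CPM, the other controls at 4.97 and 4.81 and the knockdown libraries at 4.69 to 5.02. Without control 2 the adjusted p was 0.867, and 1 member rose and 2 fell. RRM2, a subunit of ribonucleotide reductase, had 36.7, 5.76 and 31.0 CPM in the controls and 76.6 ± 18.6 CPM in the knockdown (edgeR adjusted p = 0.0923).

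Cell cycle inhibitors did not move together. CDKN1C (p57) rose from 6.90 ± 1.01 to 22.4 ± 4.25 CPM and CDKN2C (p18) from 2.29 ± 0.562 to 8.15 ± 0.625 CPM, while CDKN2B (p15) fell from 56.5 ± 21.9 to 12.5 ± 3.20 CPM. CDKN1A (p21) stood at 20.9 ± 7.34 and 21.9 ± 10.3 CPM (edgeR adjusted p = 0.917). Of 16 inhibitors and G1 cyclins 5 rose and 2 fell (7 and 2 when adjusted over the list alone). Camera called the list higher (adjusted p = 0.0447, and adjusted p = 0.836 with an estimated correlation), but not without control 2 (adjusted p = 0.257) or without knockdown 1 (adjusted p = 0.0893). The number of rises was 3 without control 1, control 2, knockdown 2 or knockdown 3, and 2 without control 3.

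Of 14 replication-dependent histone genes measured, most of them at low levels, 7 rose and none fell (12 and 0 when adjusted over the list alone), with a median log2 fold change of 1.29. HIST2H2BE rose from 9.65 ± 0.876 to 23.1 ± 2.29 CPM, and HIST1H2BC from 0.796 ± 0.127 to 2.06 ± 0.243 CPM with an adjusted p up to 0.0968 without a library. Camera called the list (adjusted p = 3.2e-06), with adjusted p = 0.139 with an estimated correlation. Histone genes share sequence, so counts of single members are uncertain, and the number of rises was 1 without control 1, control 3, knockdown 2 or knockdown 3.

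Cytosolic ribosomal protein genes had a median log2 fold change of -0.26 over 70 genes, and -0.14 without control 2 (camera adjusted p = 1.5e-05, and adjusted p = 0.836 with an estimated correlation). Only RPS20, from 738.9 ± 54.6 to 378.3 ± 14.01 CPM, and RPL23A, from 438.5 ± 34.9 to 308.1 ± 25.1 CPM, passed the test; 1 did when adjusted over the list alone. RPL23A reached an adjusted p of 0.125 without a library, and control 2 was highest for the list, at 9.78 log2 CPM against 9.37 and 9.55 in the other controls. The number that fell was 13, with 2 higher, without knockdown 1, and 1 without each other library in turn.

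For blood vessel factors the changes were mixed. Endothelin (EDN1) rose from 36.5 ± 2.46 to 144.2 ± 20.6 CPM and the inhibitor thrombospondin (THBS1) from 42.2 ± 9.57 to 155.3 ± 24.7 CPM, whereas IL8 and CXCL1 fell. PDGFB had 36.8 ± 11.2 and 23.2 ± 3.12 CPM (edgeR adjusted p = 0.0986) and VEGFA 571.0 ± 116.9 and 316.1 ± 212.5 CPM (edgeR adjusted p = 0.197). VEGFA in knockdown 1, at 561.4 CPM, lay within the control range, and in knockdown 2 and 3 it lay at 191.8 and 195.0 CPM. With a library left out, the lowest edgeR adjusted p was 0.0208 for PDGFB and 0.000902 for VEGFA. In the list of 20, 3 rose and 3 fell (4 and 5 when adjusted over the list alone; camera adjusted p = 0.642). Without knockdown 1, 4 rose and 7 fell, and without control 1, control 3, knockdown 2 or knockdown 3, 2 rose and 2 fell.

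Among genes of adhesion and invasion, the desmosomal protein DSP rose from 229.2 ± 11.4 to 437.3 ± 29.8 CPM, while the tight junction protein CLDN1 fell by 1.11 on the log2 scale, with an adjusted p up to 0.0623 without a library. E-cadherin (CDH1) had 366.6 ± 46.5 and 277.9 ± 31.1 CPM and vimentin (VIM) 0.440 ± 0.133 and 0.584 ± 0.160 CPM, and neither passed (edgeR adjusted p = 0.0845 and 0.493). With a library left out, the lowest edgeR adjusted p was 0.0156 for CDH1 and 0.265 for VIM. Of 21 members 2 rose and 6 fell (2 and 7 when adjusted over the list alone; camera adjusted p = 0.669). Without knockdown 1, 4 rose and 9 fell; none fell without control 1, control 3 or knockdown 3, and 3 fell without knockdown 2. Among TGF-beta and YAP targets 1 of 23 rose and 3 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.855). Its median was 0.0019 and its mean -0.17, so the median differed in sign from the mean and the test. Without knockdown 1, 4 rose and 5 fell, without control 2, 2 rose and 3 fell, and without any other library none passed.

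p53 targets and apoptosis regulators were not called as lists (camera adjusted p = 0.601 and 0.716). GDF15, a stress-induced cytokine, rose from 215.3 ± 29.9 to 675.4 ± 151.7 CPM, BTG2, an antiproliferative factor, from 9.81 ± 0.993 to 51.8 ± 21.8 CPM, and BCL2, which restrains apoptosis, from 1.07 ± 0.148 to 4.48 ± 0.851 CPM. Of 24 p53 targets 3 rose and 2 fell (5 and 2 when adjusted over the list alone). Of 31 apoptosis regulators 2 rose and 4 fell (3 and 5 when adjusted over the list alone). Without knockdown 1, 4 p53 targets and 8 apoptosis regulators fell. No p53 target fell without any other library, and no apoptosis regulator without control 1, control 3 or knockdown 3; without control 2, 4 apoptosis regulators rose and 2 fell, and without knockdown 2, 1 fell.

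Metabolic lists showed changes of single enzymes. PGK1, a glycolytic kinase, fell from 366.4 ± 39.9 to 100.8 ± 16.5 CPM, a log2 fold change of -1.86 ± 0.15 (SE; edgeR adjusted p = 0.00150). Glycolysis had 2 genes higher and 5 lower of 20 (3 and 5 when adjusted over the list alone; camera adjusted p = 0.855), with a median of 0.11 and a mean of -0.02, opposite in sign. Of 23 fatty acid genes none rose and 4 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.778), with a median of 0.06 against a mean of -0.04 and a downward test. The desaturase SCD was among those that fell, from 2477 ± 409.6 to 887.4 ± 301.6 CPM, with an adjusted p up to 0.0710 without a library. Of 24 cholesterol synthesis genes 3 fell, none when adjusted over the list alone (camera adjusted p = 0.0612). Oxidative phosphorylation had 1 gene higher and 1 lower of 43 (0 and 0 when adjusted over the list alone; camera adjusted p = 0.736), and 10 higher and 3 lower without knockdown 1. None of 13 mitochondrially encoded genes passed over all genes or when adjusted over the list alone (camera adjusted p = 0.385), and 9 rose without knockdown 1 (camera adjusted p = 0.000405), in which they made up 4.68% of counts against 8.41% and 8.04% in knockdown 2 and 3. Of 22 hypoxia genes 1 rose and 5 fell (1 and 7 when adjusted over the list alone; camera adjusted p = 0.138), and 12 fell without knockdown 1 (camera adjusted p = 0.00124). The mitochondrial chaperone HSPD1 fell from 729.8 ± 33.8 to 384.8 ± 37.8 CPM in a heat shock list with 1 of 16 higher and 2 lower (2 and 2 when adjusted over the list alone; camera adjusted p = 0.855). Without knockdown 1, glycolysis had 5 higher and 6 lower, fatty acid genes 5 and 6, cholesterol synthesis 2 and 3, and heat shock 4 and 3. Without control 2, 6 cholesterol synthesis genes and 2 hypoxia genes fell, and without knockdown 2 no gene of either list and 2 glycolysis genes did. Without control 1, control 3 or knockdown 3 no hypoxia, oxidative phosphorylation or cholesterol gene fell, and at most 1 gene of each other metabolic or heat shock list did.

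Non-coding genes made up 300 of the changed genes, out of 2681 tested, with 162 higher and 138 lower. The number was 38 without control 1, 177 without control 2, 33 without control 3, 793 without knockdown 1, 69 without knockdown 2 and 36 without knockdown 3. The 3 smallest adjusted p among those that rose belonged to LOC100093631, LOC101928281 and MBNL1-AS1, with log2 fold changes of 1.42 ± 0.12, 1.87 ± 0.19 and 2.12 ± 0.23 (SE). Among those that fell they belonged to LOC101929494, LINC00963 and RP11-983P16.4, with -1.86 ± 0.18, -1.09 ± 0.11 and -0.85 ± 0.10 (SE). Of 37 long non-coding RNAs of known function 4 rose and 2 fell (6 and 3 when adjusted over the list alone; camera adjusted p = 0.754). Without knockdown 1, 6 rose and 15 fell, so the balance turned toward falls, while without any other library 2 or 3 rose and none fell. KCNQ1OT1, the imprinted antisense transcript of KCNQ1, rose from 21.9 ± 1.01 to 42.4 ± 2.87 CPM, and MIR17HG, the host of a microRNA cluster that MYC induces, from 4.19 ± 0.772 to 13.1 ± 2.89 CPM. Whether counting used strand was not stated, so reads of MBNL1-AS1, GPC5-AS1 and KCNQ1OT1 could not be told from those of genes that overlap them.

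Markers of other cell types were present at unequal levels, among them LYZ at 843.3 CPM in the controls, ENO2 at 62.4, CD68 at 27.5, TUBB3 at 18.1, NES at 15.4 and TAGLN at 9.80 CPM; ENO2 and CD68 were named after their values were seen. None of 3 measured fibroblast markers and none of 7 markers of kidney packaging or neural cells passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.716 and 0.515). Of 6 immune and endothelial markers LYZ rose and CD14, VWF and CD8A fell, also when adjusted over the list alone (camera adjusted p = 0.101). CD14 stood at 2.53 ± 0.186 CPM in the controls and 0.529 ± 0.117 CPM in the knockdown, and VWF and CD8A at or below 1.77 CPM in every library, with adjusted p up to 0.136 and 0.137 without a library. Without knockdown 1, 1 immune marker rose and 4 fell and 1 kidney or neural marker rose and 1 fell; without any other library 1 immune marker fell. Of 11 HT29 epithelial genes KRT20 fell and none rose, with 5 lower without knockdown 1, 2 without control 2 and none without control 3 or knockdown 3. The sources do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.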

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

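The 4-library comparison was chosen after the data were seen. Under the 3 other scalings, limma-voom, the robust fit and both filters, the ETV5 call and all gene counts kept their direction and stayed within 1.5 times. DESeq2 called 3671 genes, within the same limit, and 453 non-coding, beyond it. The filter of 1 CPM left low genes such as PAX4 and NEUROG3 without a value, and the fibroblast list, which lost LUM, without a test. The robust fit does not enter the list tests and was not run for lists. Without a library, genes changed ranged from 415 to 6362, higher genes from 188 to 3083, lower genes from 227 to 3279, genes changed at least 2-fold from 333 to 2259 and non-coding genes from 33 to 793. With 4 libraries these were 8563, 4268, 4295, 2665 and 1083. The libraries left there were closer to each other within groups. ETV5's log2 fold change ranged from -3.51 to -1.69 without a library, and the call was lost at -3.11 and -3.16 without knockdown 2 and 3.

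A replicate block gave 1567 genes, 752 higher and 815 lower, with 140 non-coding. Same-numbered samples deviated with correlations of 0.0532, 0.0038 and -0.118, so the numbers did not pair them, and not every sample correlated best with its own number. With the block the camera adjusted p was 0.0354 for MAPK output, 0.0292 for the secretory lineage and 0.0354 for cholesterol synthesis, which all passed, and no other list call changed.

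With a correlation estimated for each list no list was called. The adjusted p was 0.139 for interferon response and histones, 0.636 for NF-kB targets and 0.836 for G1/S, G2/M, CDK inhibitors, Wnt targets, the unfolded protein response and ribosomal proteins. With fry, MAPK output (0.0225) and immune markers (0.00429) passed, while G1/S (0.607), G2/M, CDK inhibitors and Wnt targets (0.177 each), the unfolded protein response (0.146) and ribosomal proteins (0.287) did not. Interferon response, NF-kB targets and histones were called by camera and fry. Secretory genes passed with median-ratio factors (0.0487) and upper-quartile factors (0.0328). With no filter they passed at 0.0117, MAPK output at 0.0207, hypoxia at 0.0398, cholesterol synthesis at 0.0253 and immune markers at 0.0404. Without a library the adjusted p ranged from 0.00222 to 0.0957 for secretory genes, 0.0079 to 0.257 for CDK inhibitors, 0.00157 to 0.735 for cholesterol synthesis, 5.4e-05 to 0.867 for G1/S genes (downward without control 2, the highest), 0.00124 to 0.484 for hypoxia and 0.000405 to 0.909 for mitochondrially encoded genes. With 4 libraries G1/S (0.437) and CDK inhibitors (0.344) were lost, and secretory genes (0.000767), hypoxia (0.000955) and mitochondrially encoded genes (0.000379) passed. The gene CDKN1A, not called with all libraries, turned to -0.67 and passed there. Apart from these and from the size of the samples left, the cause was not tested.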

Other observations

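The tests of the antigen presentation and NRF2 lists, of the snoRNAs, of each explanation for control 2, of the swap and culture explanations for knockdown 1 and of the graded and vector explanations for interferon genes were chosen after the result was seen.

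In a list of antigen presentation genes chosen after the data were seen, 13 of 18 measured members fell and none rose, with a median log2 fold change of -1.37, and 16 were lower when adjusted over the list alone. HLA-B and HLA-C, whose reads can be shared with similar genes, went from 103.8 and 167.6 CPM in the controls to 15.3 and 25.3 CPM (SD of HLA-B 23.4 and 13.7, n = 3). ERAP1, a peptidase that trims peptides for presentation, went from 131.7 to 29.3 CPM, a log2 fold change of -2.17 ± 0.21 (SE; edgeR quasi-likelihood adjusted p = 0.00238). The number of members that fell was 5 without control 1, control 3 or knockdown 3, 6 without knockdown 2 and 18 without knockdown 1.

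Of 139 small nucleolar RNAs tested, which guide modification of ribosomal RNA, 26 rose and none fell, and 118 had a fold change above 0, with a median of 0.54 on the log2 scale at 0.852 and 1.35 CPM; the RNA selection is not stated and many snoRNAs lie within introns of other genes, so these counts are uncertain. SNORD14B, chosen after its values were seen, went from 3.43 ± 0.233 to 6.996 ± 0.182 CPM (SD, n = 3 each; edgeR quasi-likelihood adjusted p = 0.0123). The number that rose was 1 without control 1 or control 3, 11 without control 2, 32 without knockdown 1 (where 2 fell), 5 without knockdown 2 and 3 without knockdown 3. Of NRF2 targets, 1 of 21 rose and 1 fell, with 3 higher and 1 lower when adjusted over the list alone; without knockdown 1, 5 rose and 4 fell and the median turned from 0.22 to -0.26, and none fell without any other library. In knockdown 1 alone AKR1C1, which was chosen after its values were seen, stood at 276.2 CPM, against 9.01 to 13.1 CPM in the other libraries.

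Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 2584 changed genes, 1188 at least 2-fold and 300 non-coding, and the highest of the other splits gave 0 for each, so 1 split of 10 reached each count. Each other split put control and knockdown libraries in both groups, so any difference between the labels widened the spread within groups. Low counts were thus likely in advance, and they do not tell what caused the difference. For gene lists called by camera with the preset correlation, 6 of the 10 splits gave at least as many as the 9 of the real split, and the highest of the others gave 16.

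ETV5 stood 6.06 times higher in control 2 than in the mean of controls 1 and 3. A swap with a knockdown library is argued against, since its highest correlation with any of them was 0.9552, below its lowest with a control (0.9783), and no knockdown library held ETV5 at the level of controls 1 and 3. The median gene differed by -0.012 on the log2 scale, but TMM scaling centres the typical gene, so that value alone tests nothing. A scaling fault would move all genes of a library alike, whereas ETV5 differed by 2.60. Before scaling, ETV5 had 16448 counts in control 2, against 2377 and 2205 in controls 1 and 3. These ETV5 values argue against scaling. A single wrong label or a construct that expresses ETV5 may account for it and cannot be excluded from counts. G2/M genes in the same library lay 1.71 lower in median log2 than in controls 1 and 3. Control 2, and knockdown 2 and 3, were also set against controls 1 and 3 over 2479 genes changed 2-fold with 4 libraries. Their differences correlated at 0.348, or 0.289 and 0.332 with a separate control as each baseline. Of 405 genes 2-fold apart in control 2, 117 (28.9%) went opposite to the knockdown. Among these genes control 2, with the most ETV5, moved more often with the knockdown than against it. Controls 1 and 3 both selected the genes and served as baselines, however. Their errors can pull the compared differences the same way, also with a separate control as each baseline. The comparison therefore does not decide how control 2 relates to the knockdown. Control 2 is a single library, and no biological explanation was tested.

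Knockdown 1 lay between the controls and knockdown 2 and 3. Admixed control RNA would imply the same control share in every gene group. The median implied share was 57.2% for the unfolded protein response (quartiles 43.9% and 74.4%) and 1.37% for interferon genes (quartiles -1.82% and 18.2%). This difference of 55.9 points argues against admixture. Its SE of 7.68 came from resampling genes as if independent. It may be too small, since the estimated correlation within the unfolded protein response list was 0.611. A swap with a control is argued against by ETV5, at 29.8% of the mean of controls 1 and 3. The correlations across genes do not decide this, at 0.9618 with control 1 and 0.9634 with knockdown 2. Another culture state or hairpin may account for the 219 genes in knockdown 1 that lay over 2-fold outside the range of the other 5 libraries, 76 above and 143 below, against 348 in control 2 and 32 to 56 in each other library, and the labels do not say.

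Interferon response genes were lower in all 3 knockdown libraries. Immune cell RNA in the controls is argued against, because 8 leukocyte genes had a median of 0.0255 CPM there, with PTPRC at 0.0233 and TYROBP at 0.0255 CPM, although CD4 stood at 1.13 CPM against 0.635 in the knockdown and CD14 and CD8A fell. Dependence on the ETV5 level is a candidate explanation. Control 2, with the most ETV5, had the lowest list mean of the controls, however, at 3.99 log2 CPM against 4.05 and 4.33 in controls 1 and 3. Its difference from their mean was -0.20, smaller than the gap between controls 1 and 3. That library thus shows no rise of the list with ETV5, but a single library decides nothing. A response to the control vector, or separate handling of the groups, may also account for it and cannot be told apart from the knockdown, because no untreated cells were analysed here; IFNB1 and IFNL1, which encode interferons, had 8 reads in the controls, 5 and 2 of them (IFNB1 and IFNL1) in control 3 and 1 in control 1, and 0 in the knockdown libraries.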
